A study of Homo sapiens with 24 samples.

How the data were processed

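RNA of 4 established triple-negative breast cancer lines (HCC38, BT549, MDA-MB-157 and MDA-MB-231) was measured at 0, 24 and 72 h of 2 µM cisplatin. Per the labels, RNA was extracted with a QIAGEN RNAeasy kit, labelled with biotin through an Ambion MessageAmp kit and hybridised to single-colour Illumina bead arrays, and cells grew under the conditions advised by ATCC. How well these kits capture small RNAs and histone mRNAs was not tested, so the signals of such genes may not follow their RNA levels. The 24 arrays formed 12 groups (line by time) of 2 replicates, which the series' design text calls independent, on 2 slides of 12 arrays. Each slide held 1 array of every group. All 24 arrays were used, and 0 per-sample columns were left out.

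The intensity values were deposited by the authors as non-normalized bead intensities per probe, and the software that summarised them is not stated. Their level shows no background subtraction. Beside each intensity stands a detection p-value, per the file headers, which gives the chance that a probe's intensity comes from the array's negative controls, as read from its fall with intensity; how the authors computed it is not stated. The log2 values that the authors deposited in a second table carry no stated method. Once its probes were matched to the intensity table by value, each log2 value equalled the log2 intensity minus the array's 75th percentile and minus the probe's median over the 24 arrays. The identifiers of that table did not correspond to its values. By identifier its values correlated with log2 intensity at -0.0073 to 0.0073 per array, against at least 0.99999 after matching by value. Only 33 of 47322 probes kept the same identifier, and 47319 matched within a distance of 0.02. Over 3017 genes with 2 probes, the 2 probes correlated over the arrays at a median of 0.777 in the normalized intensity table (0.014 for random pairs). In the second table the median was 0.303 by its own identifiers (0.311 for random pairs) and 0.773 after matching by value. The second table was therefore used only as an alternative, after matching by value.

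Probe symbols came from the platform annotation and were looked up by Entrez gene identifier in the RefSeq gene table of GRCh38.p14. Of 47322 probes, 30112 had 1 symbol, 8 had several and 17202 had none, and only probes with 1 symbol were tested as genes. The 30112 probes covered 20046 genes. Background was corrected with the normexp method of limma 3.58.1 in R 4.3.3. The negative controls were inferred from the detection p-values, since the files hold no control probes, and an offset of 16 was added. Quantile normalization and a log2 transform followed. Probes with a detection p under 0.05 on at least 2 arrays were kept, and each gene was represented by its probe with the highest mean, which left 14807 genes. Where a called gene has other probes that passed the filter, their values are given if their log2 change differs by more than 1.5 times. Where no array of the dimmer group detected a gene, only the least fold change is given, except for the differences between lines at 0 h.

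limma fitted 1 mean per group on all 24 arrays, which leaves 12 residual degrees of freedom, and moderated the spread with 6.87 prior degrees of freedom. Each line was compared at 24 h and 72 h with its own 0 h. The averages over the 4 lines, and the change from 24 h to 72 h, weighted the lines equally. Their error is the spread between replicates within a line, so they do not extend to other lines. F tests compared the lines at 0 h and tested whether their changes differed. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the number at an unadjusted p under 0.05 is given beside low counts, where chance alone gives 740. On simulated data with the same layout, 65.7% of genes changed by 0.5 log2, 97.0% of those changed by 1 and 100% of those changed by 2 were recovered in the average at 72 h, with 8 false calls. For a single line the shares were 4.48%, 58.2% and 98.5%, with 1 false call. A simulation without change gave 0 calls. The simulated noise was independent between genes and held no deviation of an array that many genes share. The real arrays have such deviations, so these shares and false calls can be too favourable for them.

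The tests, the 27 gene lists, the genes to be named and the alternatives were chosen before the data were examined. Lists were tested with camera in limma, with a preset correlation of 0.01 and with the correlation estimated from the data, adjusted over the 27 lists. Changes of list members when adjusted over the list alone are also counted. After the camera results were seen, 2 further tests of the lists were added. These test the list's mean log2 value per array, with limma over the 27 lists and, for the averages, with an exact permutation of the time labels within each line (1296 arrangements, smallest possible p 0.0015). Each list was thus tested in 4 ways for the averages, and the results of all 4 are given for the lists called at 24 h and 72 h.

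The genes named were the 10 largest rises and falls in the average at 72 h and the 6 largest of each at 24 h, among called genes with the same sign in the 4 lines. For the change from 24 h to 72 h they were the 4 largest of each. In each line they were the 5 largest rises and falls at 72 h and the 3 largest of each at 24 h. Up to 8 genes whose change differed between lines and the 4 largest excesses of each line at 0 h were also named. For each list, up to 4 called members were named or, with none called, up to 2 with the smallest p. Genes of the cisplatin response were named whatever their values, of which BIRC3 had no named probe and IL1B did not pass the filter. The exceptions, named after their values were seen, are LRMDA, RASGRP3, CDKN1B and ASF1A in BT549 and the tubulin and interferon pathway genes of the closing section. The genes that section names as highest or lowest on MDA-MB-231 0 h replicate 2 were also picked from their values.

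The alternatives were no background correction, normexp on the intensities alone with an offset of 50, median scaling, the authors' log2 values, no detection filter, a stricter filter (p under 0.01 on at least 12 arrays), all probes, a slide block, a replicate block, array quality weights (statmod 1.5.0), a line's own 6 arrays, line means as replicates, each slide alone, and leaving out each line and each array in turn. The array quality weights came out equal for the 2 arrays of each group (0.525 for both MDA-MB-231 arrays at 0 h). They therefore weight whole groups and cannot single out 1 replicate. With 1 array left out, the lone array of its group is assumed to vary like the others. Without MDA-MB-231 0 h replicate 1, that line's baseline is replicate 2 alone, which stood apart from the line's other arrays.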

Results

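The series followed how 4 triple-negative breast cancer cell lines changed gene expression under cisplatin, a platinum drug that crosslinks DNA. HCC38, BT549, MDA-MB-157 and MDA-MB-231 are established lines from breast tumours that lack hormone receptors and amplified HER2. Each received 2 µM cisplatin and was collected at 0, 24 and 72 h, with 2 independent replicates per time according to the series' design text. This gave 24 single-colour Illumina bead arrays in 12 groups of 2. Time-matched untreated cultures were not analysed here, so drug exposure and time in culture changed together in every comparison. Between 18303 and 21976 of 47322 probes (38.7% to 46.4%) were detected per array, and 14807 named genes were tested. The number of arrays per group, 2, limits the precision. Replicates correlated across genes at 0.977 to 0.991. The 2 MDA-MB-231 arrays at 0 h lay farthest apart, with 765 genes over 2-fold apart, against 527 for BT549 at 72 h and 70 for MDA-MB-231 at 72 h. The arrays also differed in brightness. The 75th percentile of intensity was 281 and 222 on the BT549 arrays at 0 h, and 166 and 160 at 72 h. Quantile normalization removes such differences. With each array scaled to its median instead, the median log2 change of all genes moved to -0.40 at 24 h and -0.47 at 72 h in BT549, and to -0.28 and -0.22 in HCC38. It moved to 0.16 and 0.12 in MDA-MB-231, and to 0.17 at 72 h in MDA-MB-157. Changes of gene lists under that scaling are therefore also given relative to all genes.

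The lines differed widely before the drug. In BT549, COL1A2, a chain of type I collagen, lay 6.44 log2 (SE 0.50) above the mean of the other 3 lines. THY1, a surface glycoprotein of mesenchymal cells, lay 6.31 above, TAGLN, an actin-binding protein of smooth muscle, 5.93, and BAIAP2L2 5.74. HCC38 stood out by KLK5, a secreted serine protease, at 8.35 above the other lines, CA2, a carbonic anhydrase, at 7.37, CT45A3, a cancer-testis antigen, at 7.26, and RARRES1, a retinoid-responsive gene, at 7.09. MDA-MB-157 had the neuropeptide gene NPY at 6.32, PDGFRB, a growth factor receptor of mesenchymal cells, at 6.07, the scavenger receptor gene COLEC12 at 5.67 and CTAG1A, another cancer-testis antigen, at 5.53. MDA-MB-231 had RAC2, a small GTPase of blood cells, at 6.04, C19orf33 at 5.64, FOXA2, a transcription factor of endoderm, at 5.43 and the interferon-induced gene IFI27 at 5.30. CT45A3 and CTAG1A have near-identical copies, so which copy was measured is uncertain. Some of these genes lay near background in the other lines. On the MDA-MB-231 arrays at 0 h, PDGFRB read 4.73 and 4.47 and RARRES1 4.58 and 4.76. Such excesses are differences from background and are best read as least values. limma's F test called 9891 of the 14807 genes (66.8%) different between the lines at 0 h, and the adjusted p of the genes named here ran from 1.4e-17 to 7.9e-07.

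At 24 h, PKMYT1, the kinase that keeps CDK1 inactive before mitosis, rose by 0.68 log2 (SE 0.10, limma adjusted p = 0.015) on the average of the 4 lines, and its other probe read 0.90. LRMDA, a gene of melanocyte differentiation, fell by 0.66 (SE 0.10, adjusted p = 0.029), with detection on 1 of 8 arrays at 24 h and 4 of 8 at 0 h. Genes of DNA replication lay higher as a group. Of 31 measured G1/S and DNA replication genes, 29 lay above 0 with a median of 0.32, and 18 rose when adjusted over the list alone, although none passed over all genes (camera adjusted p = 5.1e-18, and adjusted p = 0.23 with an estimated correlation). ORC1, a subunit of the origin recognition complex, was at 0.65 and RRM1, a subunit of ribonucleotide reductase, at 0.39. Fanconi anaemia and homologous recombination genes, which act on crosslinks and broken ends, had a median of 0.25 with 17 of 20 above 0 and 11 risen when adjusted over the list alone (camera adjusted p = 2.9e-10, and adjusted p = 0.20 with an estimated correlation). BLM, a helicase, was at 0.64 and EXO1, an exonuclease, at 0.51. Of the other lists called with the preset correlation, translesion synthesis genes had a median of 0.10 (adjusted p = 0.023, and adjusted p = 0.20 with an estimated correlation), with POLQ at 0.32, and metallothionein genes 0.26 with 8 of 8 above 0 (adjusted p = 6.4e-04, and adjusted p = 0.31 with an estimated correlation), with MT2A at 0.38. Lower lists were histone genes at -0.26 with 0 of 15 above 0 (adjusted p = 8.9e-06), with H2BC21 at -0.58, cholesterol and lipid synthesis genes at -0.16 (adjusted p = 1.8e-04), with HMGCS1 at -0.51, and ATF4 and unfolded protein response genes at -0.18 (adjusted p = 0.0014), with CTH at -0.57. With an estimated correlation these 3 had adjusted p = 0.31, adjusted p = 0.52 and adjusted p = 0.67. None of these directions turned under median scaling.

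Each list's mean per array was also tested. The mean of the Fanconi anaemia and homologous recombination genes was 0.26 log2 higher at 24 h (SE 0.07) with limma's adjusted p = 0.072 and an exact permutation of the time labels within lines giving adjusted p = 0.042. That of the G1/S and DNA replication genes was 0.31 higher (SE 0.10) with limma's adjusted p = 0.072 and an exact permutation adjusted p = 0.062. Without MDA-MB-231 0 h replicates 1 and 2 the Fanconi mean was 0.33 and 0.19, and the G1/S mean 0.42 and 0.21. The first of these settings leaves only replicate 2, which stood apart from the line's other arrays, as that line's 0 h baseline. The limma tests of the Fanconi and G1/S means depended on the settings, with adjusted p of 0.742 and 0.716 with median scaling. Both passed with array quality weights (0.025 and 0.026), with a replicate block within each line (0.022 and 0.024) and without HCC38 0 h replicate 1 (0.031 and 0.039). The Fanconi mean also passed without background correction (0.033) and with normexp and an offset of 50 (0.049). The quality weights were equal for the 2 arrays of each group, so they could not single out MDA-MB-231 0 h replicate 2. The other 5 lists called by camera did not pass as means, with 0.12 for translesion synthesis genes (limma and exact adjusted p 0.072 and 0.062), -0.25 for histone genes (0.151 and 0.062), 0.27 for metallothionein genes (0.285 and 0.142), -0.22 for cholesterol and lipid synthesis genes (0.346 and 0.298) and -0.21 for ATF4 genes (0.479 and 0.493). The ATF4 call ended without MDA-MB-231 0 h replicate 2 (median -0.01, camera adjusted p = 0.943, the highest over its alternatives, from 6.6e-15). The translesion call ended without MDA-MB-231 0 h replicate 1 (0.054), MDA-MB-157 0 h replicate 2 (0.051), MDA-MB-231 24 h replicate 1 (0.062) or MDA-MB-157 24 h replicate 2 (0.063), and over its alternatives the adjusted p ran from 0.0076 to 0.297. Without MDA-MB-231 0 h replicate 1 the medians were -0.35 for the ATF4 list, -0.26 for the cholesterol list and 0.06 for the translesion list, and without MDA-MB-231 0 h replicate 2 the cholesterol list was at -0.08. The translesion median was 0.16 without HCC38 0 h replicate 1, 0.15 without MDA-MB-231 24 h replicate 2 and 0.05 without BT549 24 h replicate 2. The 2 single genes were called where 1296 had an unadjusted p under 0.05, against 740 by chance. That count of 2 rested on single arrays. It moved to 130 without MDA-MB-231 0 h replicate 1, to 7 without HCC38 0 h replicate 1 and to 4 without BT549 72 h replicate 1 or 2. It moved to 1 without MDA-MB-157 0 h replicate 1, BT549 24 h replicate 2, HCC38 24 h replicate 2, either MDA-MB-231 72 h array or either HCC38 72 h array. Neither gene was called without MDA-MB-231 0 h replicate 2, BT549 0 h replicate 1, HCC38 0 h replicate 2, MDA-MB-231 24 h replicate 2, either MDA-MB-157 24 h array or HCC38 24 h replicate 1.

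After 72 h, 179 genes differed from 0 h on the average of the 4 lines, 75 of them higher and 104 lower. Of the 179, 154 had the same sign in every line, against 18.6% of all genes. Being called on that average by itself favours the same sign, so this share is no evidence that the lines agree. Among the called genes with the same sign in all 4 lines, the largest rises included HYAL3, a hyaluronidase, at 0.94 log2 (SE 0.12, limma adjusted p = 0.0034), CKB, the brain-type creatine kinase, at 0.85 (SE 0.11, adjusted p = 0.0034), and CSRP1, a LIM-domain protein of muscle, at 0.72 (SE 0.10, adjusted p = 0.0034). TK1, the thymidine kinase of S phase, rose by 0.75 (SE 0.15, adjusted p = 0.018) and STING1, an adaptor in the sensing of cytosolic DNA, by 0.68 (SE 0.13, adjusted p = 0.021). The other rises among the 10 largest of this kind were SNORD13, a small nucleolar RNA, at 1.01, WDR62, a spindle pole protein, at 0.75, TYMSOS at 0.73, CCDC15 at 0.72 and TUBB2A, a beta-tubulin with a near-identical copy, at 0.65. The largest falls of this kind included LHPP, a histidine phosphatase, at -0.87 (SE 0.15, adjusted p = 0.011), LRP8, a lipoprotein and reelin receptor, at -0.79 (SE 0.12, adjusted p = 0.0043), and CLYBL, a mitochondrial lyase, at -0.78 (adjusted p = 0.0057). RRAGB, a GTPase of amino acid sensing, fell by 0.71 (adjusted p = 0.030). The remaining falls among the 10 largest were ANXA2R at -0.87, BEND6 at -0.81, ZNF25 at -0.81, ANKRD10 at -0.74, ECHDC2 at -0.72 and SPRYD3 at -0.69. CLYBL was detected on 4 of 8 arrays at 72 h and 7 of 8 at 0 h, and BEND6 on 5 of 8 and 6 of 8. Other probes read smaller changes, with 0.40 for CCDC15, -0.48 for LRP8, -0.48 for ANKRD10, -0.27 for BEND6 and -0.47 and -0.15 for RRAGB. CDKN1A, the cell cycle inhibitor p21, rose by 0.77 (SE 0.18, adjusted p = 0.040), while its other probe read 0.09.

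**Figure D1:**
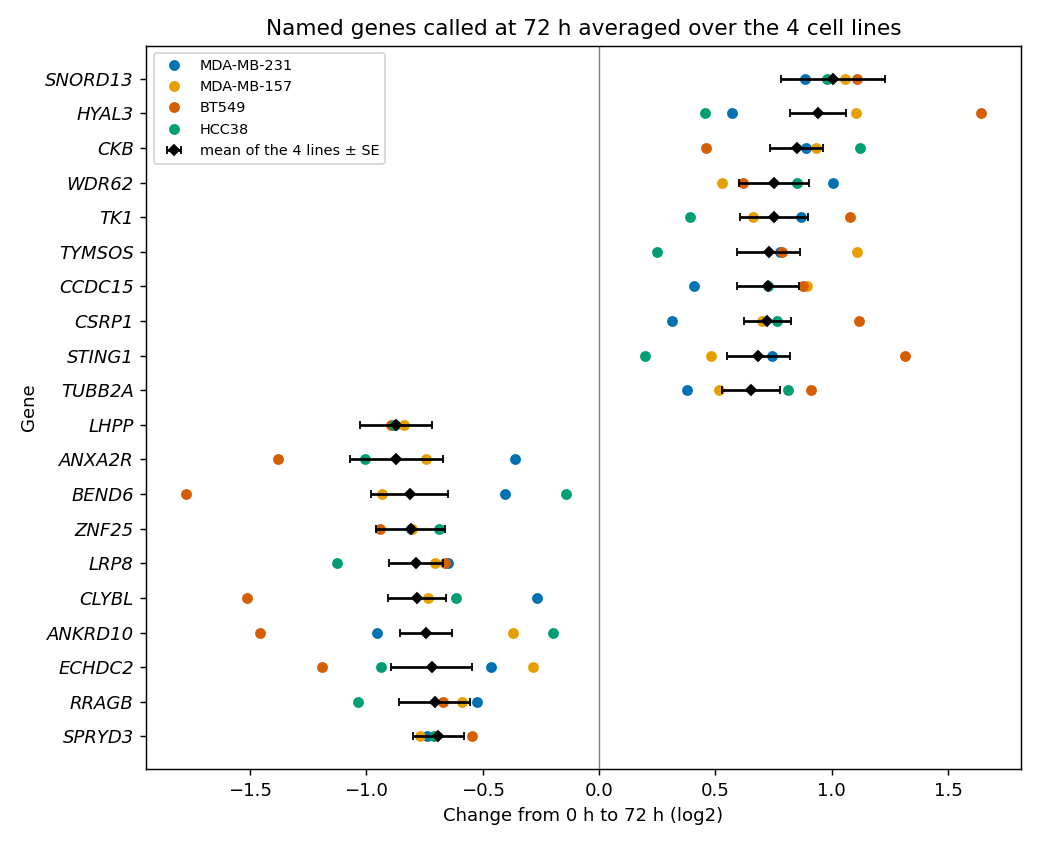
Log2 change from 0 h to 72 h of cisplatin for the 10 largest rises and 10 largest falls on the average of the lines, among called genes chosen for the same sign in all 4; the horizontal axis is the log2 change, small dots are the 4 cell lines (means of 2 arrays), and diamonds with bars are the average and its SE. HYAL3 averaged 0.94 and LHPP -0.87.

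These 72 h calls depended on how many arrays shared them. Of the 21 called genes just named, 9 stayed past the threshold without any 1 of the 24 arrays: HYAL3, CKB, CCDC15, CSRP1, LHPP, LRP8, CLYBL, ANKRD10 and SPRYD3. The highest adjusted p of HYAL3 was then 0.020, that of TK1 0.072 without MDA-MB-157 72 h replicate 2, that of STING1 0.073 without that array, and that of CDKN1A 0.123 without it. Over all alternatives the adjusted p ran from 2.5e-04 to 0.349 for HYAL3, 1.1e-04 to 0.538 for TK1, 0.0053 to 0.547 for STING1 and 0.013 to 0.632 for CDKN1A. Leaving out MDA-MB-231 0 h replicate 1 gave 541 genes and BT549 72 h replicate 1 gave 322. The count fell to 106 without MDA-MB-231 0 h replicate 2, to 88 and 56 without MDA-MB-157 0 h replicates 1 and 2, to 97 and 65 without BT549 0 h replicates 1 and 2, and to 73 without HCC38 0 h replicate 2. It fell to 92 and 51 without MDA-MB-231 72 h replicates 1 and 2, to 31 without MDA-MB-157 72 h replicate 2, to 82 without BT549 72 h replicate 2, and to 79 and 52 without HCC38 72 h replicates 1 and 2. The calls ended with median scaling, and the authors' values gave 51. Leaving out all BT549 arrays left 1 call.

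Of 32 G2/M and mitosis genes, 31 lay above 0 on the average of the lines, with a median of 0.18 (camera adjusted p = 1.4e-07, and adjusted p = 0.45 with an estimated correlation). G1/S and DNA replication genes had a median of 0.28, with TK1 risen over all genes and 5 of 31 when adjusted over the list alone (adjusted p = 1.4e-07, and adjusted p = 0.45 with an estimated correlation). Fanconi anaemia and homologous recombination genes were at 0.25, with 9 of 20 risen when adjusted over the list alone (adjusted p = 1.8e-05, and adjusted p = 0.36 with an estimated correlation), among them BARD1, the partner of BRCA1, at 0.49. Interferon-stimulated genes had a median of 0.39, with 25 of 26 above 0, OAS1 (0.82) and IFIT3 (0.78) risen over all genes and 8 when adjusted over the list alone (adjusted p = 2.1e-09, and adjusted p = 0.36 with an estimated correlation). Without the BT549 arrays the median of the interferon list was -0.03. Metallothionein genes, which bind metal ions, were at 0.38 with 8 of 8 above 0 (adjusted p = 8.9e-05, and adjusted p = 0.33 with an estimated correlation). NRF2 and glutathione genes were lower at -0.23, with 1 of 16 above 0 and 3 fallen when adjusted over the list alone (adjusted p = 1.1e-04, and adjusted p = 0.40 with an estimated correlation), and AKR1B10, an aldo-keto reductase, was at -0.67. Pro-apoptotic genes were at 0.14 (adjusted p = 0.0049, and adjusted p = 0.21 with an estimated correlation), with PMAIP1 at 0.30. NF-kB and inflammatory cytokine genes were at 0.12 (adjusted p = 0.038, and adjusted p = 0.56 with an estimated correlation), and cholesterol and lipid synthesis genes at -0.15 (adjusted p = 0.018, and adjusted p = 0.75 with an estimated correlation). None of these 9 directions turned under median scaling. Without MDA-MB-231 0 h replicate 2 the G2/M median was 0.083, the G1/S median 0.151 and the cholesterol median -0.08, and without BT549 72 h replicate 2 the metallothionein median was 0.25. The NF-kB median was 0.06 without MDA-MB-231 0 h replicate 1 and 0.07 without BT549 0 h replicate 2. The cholesterol median was -0.30 without MDA-MB-231 0 h replicate 1, -0.23 without BT549 0 h replicate 2, -0.09 without HCC38 0 h replicate 2, and -0.06 and -0.24 without MDA-MB-231 72 h replicates 1 and 2.

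Tested as list means at 72 h, translesion synthesis genes were 0.14 log2 higher (SE 0.04, limma adjusted p = 0.046, exact permutation adjusted p = 0.042) and pro-apoptotic genes also 0.14 (SE 0.04, limma adjusted p = 0.046, exact permutation adjusted p = 0.042). By camera the translesion list, with a median of 0.06, had not passed (adjusted p = 0.060, and adjusted p = 0.33 with an estimated correlation). Both limma calls ended with median scaling, with the authors' values and with array quality weights. The translesion call also ended without any 1 of 17 of the 24 arrays (highest adjusted p = 0.126, MDA-MB-157 0 h replicate 2). It was kept only without MDA-MB-231 0 h replicate 1 or 2, HCC38 0 h replicate 1, MDA-MB-231 24 h replicate 1 or 2, MDA-MB-157 72 h replicate 2 or BT549 72 h replicate 1. The pro-apoptotic call ended without any 1 of 13 arrays (highest adjusted p = 0.123, BT549 72 h replicate 2). Those 13 were both 0 h arrays of MDA-MB-157 and BT549, both 24 h arrays of these lines, both MDA-MB-231 72 h arrays, MDA-MB-157 72 h replicate 1, BT549 72 h replicate 2 and HCC38 72 h replicate 2. The other 8 lists called by camera did not pass as means. They were at 0.22 for Fanconi anaemia and homologous recombination genes (limma and exact adjusted p 0.060 and 0.073), 0.40 for metallothionein genes (0.060 and 0.073), -0.25 for NRF2 genes (0.078 and 0.092), 0.41 for interferon-stimulated genes (0.109 and 0.466) and 0.19 for G2/M genes (0.109 and 0.466). G1/S genes were at 0.24 (0.111 and 0.146), NF-kB genes at 0.14 (0.308 and 0.527) and cholesterol genes at -0.18 (0.304 and 0.466). The camera call of the NF-kB list ended without 10 of the 24 arrays (highest adjusted p = 0.229, HCC38 0 h replicate 2) and that of the cholesterol list without 6 (highest adjusted p = 0.279, MDA-MB-231 72 h replicate 1). Over all alternatives these adjusted p ran from 6.6e-04 to 0.616 and from 1.3e-04 to 0.752. Beyond CDKN1A, genes picked in advance for their place in the cisplatin response did not pass at 72 h. Damage and p53 response genes among them were GADD45A at 0.46, TNFRSF10B at 0.09, MDM2 at 0.07, GDF15 at 0.05, BBC3 at 0.03 and ATF3 at -0.11. MDM2 was detected on only 3 of 8 arrays at 72 h and 6 of 8 at 0 h, so its value lay near background. BRCA1 was at 0.44, TOP2A at 0.28, MKI67 at 0.16, CCNB1 at 0.13, CCNE2 at 0.03, PLK1 at 0.02, ERCC1 at -0.04, LMNB1 at -0.22 and MYC at -0.28. CCNE2 also lay near background, with detection on 2 of 8 arrays at 72 h and 1 of 8 at 0 h. CXCL8 was at 0.64, IL6 at 0.36, MT2A at 0.35, BCL2L1 at 0.14 and MCL1 at -0.19, and the copper and platinum transporter genes SLC31A1, ATP7A and ATP7B at 0.05, -0.17 and -0.22. At 24 h none of these genes passed. They then ranged from GDF15 at -0.70 to BRCA1 at 0.45. GDF15 lay 3.09 log2 higher on MDA-MB-231 0 h replicate 2 than on the line's other 5 arrays. Over the alternatives its 72 h value ran from -0.39 to 0.60 and it passed in 1, without the MDA-MB-231 arrays (0.60, adjusted p = 0.024). At 24 h GDF15 ran from -1.14 to -0.26 and its adjusted p from 1.8e-04, without MDA-MB-231 0 h replicate 1, to 0.975. MT2A had the lowest p (0.38, adjusted p = 0.29). The p53 target list had a median of 0.03 on the average at 72 h (camera adjusted p = 0.42), with CDKN1A the only member risen. As a mean it was at 0.07 (limma adjusted p = 0.245), and at 0.10 (adjusted p = 0.040) without MDA-MB-231 0 h replicate 2. Lists never called in any comparison had mean changes at 72 h of -0.03 (epithelial and keratin), -0.10 (immediate early and AP-1), 0.08 (haematopoietic markers), -0.03 (ribosomal proteins), -0.03 (luminal and hormone receptor), 0.03 (nucleotide excision repair), 0.08 (endothelial markers) and -0.02 (platinum and drug transporters), with limma adjusted p of 0.30 to 0.78.

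**Figure D2:**
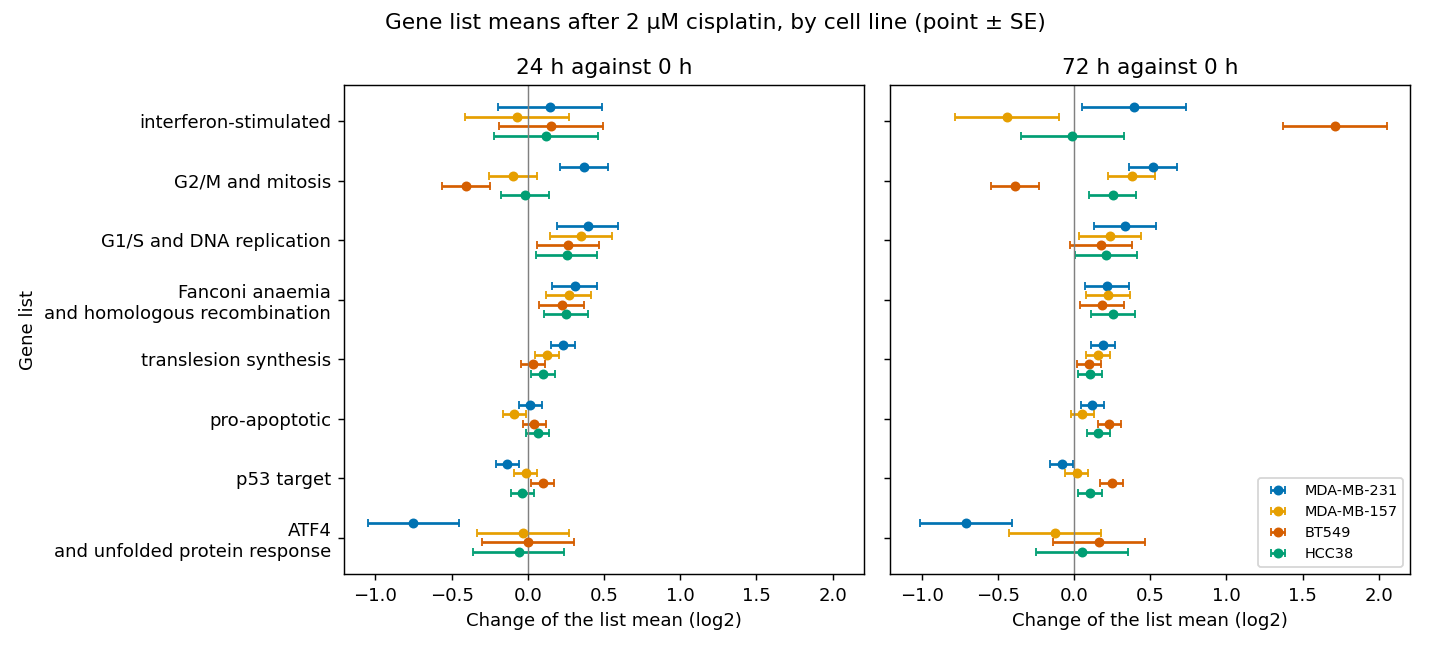
Mean log2 change from 0 h of 8 gene lists in each cell line at 24 h and 72 h of cisplatin; the horizontal axis is the change of the list mean in log2 units, points are the difference between 2 arrays at each time and 2 at 0 h, and bars are the SE from limma. Interferon-stimulated genes reached 1.71 in BT549 at 72 h, and G2/M genes lay at -0.39 there but at 0.52 in MDA-MB-231 (0.17 without its 0 h replicate 2); under median scaling the interferon mean in BT549 was 1.19.

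Between 24 h and 72 h, the largest rises on the average of the lines, among called genes with the same sign in all 4, were those of 4 small RNA genes. SNORD3A, the U3 small nucleolar RNA of ribosomal RNA processing, rose by 0.97 log2 (SE 0.17, limma adjusted p = 0.036), its near-identical copies SNORD3D by 0.96 and SNORD3C by 0.84, and RNU4-2, the U4 RNA of the spliceosome, by 0.83 (SE 0.13, adjusted p = 0.032). LRP8 fell by 0.69 (SE 0.12, adjusted p = 0.036), and its other probe read -0.45. COQ3, a methyltransferase of ubiquinone synthesis, fell by 0.57, H1-10, a linker histone, by 0.55 and ALG9, a mannosyltransferase, by 0.52. Of 15 histone genes, H2BC11 (0.85), H2BC5 (0.79) and H3C4 (0.72) rose over all genes and 8 when adjusted over the list alone (median 0.29, camera adjusted p = 4.2e-06, and adjusted p = 0.34 with an estimated correlation). Near-identical copies leave open which histone or SNORD3 gene changed. The capture of small RNAs and histone mRNAs by the kits used was not tested, so these are changes of probe signal. G2/M and mitosis genes were at 0.24, with 8 of 32 risen when adjusted over the list alone (adjusted p = 1.5e-12, and adjusted p = 0.34 with an estimated correlation) and CCNB1, the mitotic cyclin, at 0.43. NF-kB and inflammatory cytokine genes were at 0.19 (adjusted p = 1.5e-04, and adjusted p = 0.34 with an estimated correlation), with the chemokine gene CXCL8 at 1.00, and interferon-stimulated genes at 0.32 (adjusted p = 2.4e-07, and adjusted p = 0.41 with an estimated correlation), although at -0.07 without the BT549 arrays. Pro-apoptotic genes were at 0.14, lysosome and autophagy genes at 0.08 and NRF2 and glutathione genes at -0.18 (adjusted p = 0.0051, 0.021 and 0.0051, and adjusted p = 0.18, 0.71 and 0.54 with an estimated correlation). None of these directions turned under another scaling. As list means none passed, and limma's lowest adjusted p was 0.081. Without BT549 24 h replicate 2 the interferon median was 0.18. The NRF2 median was -0.12 without BT549 24 h replicate 1, -0.07 without BT549 72 h replicate 2 and -0.10 without HCC38 72 h replicate 2. The lysosome median was 0.14 without BT549 24 h replicate 1, 0.02 without BT549 24 h replicate 2, 0.04 without BT549 72 h replicate 1 and 0.13 without BT549 72 h replicate 2.

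In all, 22 genes differed between 24 h and 72 h, 16 higher and 6 lower (72.7% higher), with 1518 at an unadjusted p under 0.05. Without background correction the split was 25 higher and 21 lower (54.3%), with normexp and an offset of 50 it was 25 and 16 (61.0%), and with the authors' values 1 and 0. The calls ended with median scaling. None of the 8 genes named first stayed called without every array in turn, and their highest adjusted p was 0.195, for H1-10 without MDA-MB-157 72 h replicate 2 (0.018 to 1.00 over all alternatives). The lysosome call ended without BT549 24 h replicate 2 (adjusted p = 0.430), BT549 72 h replicate 1 (0.205), MDA-MB-157 72 h replicate 2 (0.105), MDA-MB-157 24 h replicate 2 (0.069), MDA-MB-231 72 h replicate 2 (0.062) or HCC38 72 h replicate 2 (0.058), and the NRF2 call without the last of these (0.058). Over all alternatives these adjusted p ran from 1.8e-04 to 0.706 and from 2.8e-04 to 0.536. The count of 22 moved to 63 without BT549 72 h replicate 1. It moved to 13 without either HCC38 0 h array, to 9 without either BT549 0 h array or MDA-MB-157 24 h replicate 2, to 8 without HCC38 72 h replicate 1, to 3 without MDA-MB-231 24 h replicate 2 and to 2 without either MDA-MB-157 0 h array. It moved to 1 without MDA-MB-157 24 h replicate 1, HCC38 24 h replicate 1 or BT549 72 h replicate 2. No call was left without MDA-MB-231 24 h replicate 1, BT549 24 h replicate 2, HCC38 24 h replicate 2, either MDA-MB-231 72 h array, MDA-MB-157 72 h replicate 2 or HCC38 72 h replicate 2.

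In MDA-MB-231, STAT4, a transcription factor that acts downstream of interleukin 12, rose by 1.61 log2 at 72 h (3.06-fold, SE 0.23, limma adjusted p = 0.021). Cell cycle genes lay higher at both times. The median of 32 G2/M and mitosis genes was 0.36 at 24 h (camera adjusted p = 1.4e-09, and adjusted p = 0.58 with an estimated correlation). It was 0.51 at 72 h, with 32 of 32 above 0 and 13 risen when adjusted over the list alone (adjusted p = 3.2e-17, and adjusted p = 0.53 with an estimated correlation). TOP2A, the topoisomerase of chromosome segregation, was at 0.69 and 0.73. G1/S and DNA replication genes were at 0.35 and 0.36 (adjusted p = 2.3e-07 and 4.8e-05), with MCM10 at 0.83 at 24 h, and Fanconi anaemia and homologous recombination genes at 0.34 and 0.30 (adjusted p = 3.2e-04 and 0.018), with FANCB at 0.82 at 72 h. Both lists had adjusted p = 0.58 at 24 h and adjusted p = 0.62 at 72 h with an estimated correlation. ATF4 and unfolded protein response genes were lower, at -0.80 with 1 of 23 above 0 at 24 h (adjusted p = 6.0e-11, and adjusted p = 0.58 with an estimated correlation) and at -0.57 with 0 of 23 above 0 at 72 h (adjusted p = 9.7e-10, and adjusted p = 0.53 with an estimated correlation). PHGDH, an enzyme of serine synthesis, was at -1.11 and -1.12, and HSPA5, a chaperone of the endoplasmic reticulum, at -1.73 at 72 h. Translesion synthesis (0.21) and housekeeping genes (0.20) passed at 24 h (adjusted p = 0.035 each), and interferon-stimulated (0.41, adjusted p = 4.8e-04) and ribosome biogenesis genes (-0.28, adjusted p = 0.021) at 72 h. With an estimated correlation these 4 had adjusted p = 0.46, adjusted p = 0.58, adjusted p = 0.62 and adjusted p = 0.62. None of these directions turned under median scaling.

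These MDA-MB-231 changes were measured against a 0 h group in which replicate 2 stood apart from the line's other 5 arrays. Without it, the mean of the ATF4 list went from -0.75 to -0.02 at 24 h and from -0.71 to 0.02 at 72 h. The G1/S mean at 24 h went from 0.39 to -0.03, and the G2/M mean from 0.37 to 0.02 at 24 h and from 0.52 to 0.17 at 72 h. The G1/S mean at 72 h went from 0.33 to -0.09, the Fanconi mean from 0.31 to 0.03 at 24 h and from 0.22 to -0.06 at 72 h, the housekeeping mean at 24 h from 0.22 to 0.00 and the interferon mean at 72 h from 0.40 to 0.18. The translesion mean at 24 h (0.23 and 0.26) and the ribosome biogenesis mean at 72 h (-0.22 and -0.20) stayed near their values. At 24 h limma called 0 genes, with 1269 at an unadjusted p under 0.05 and no other tool run. Leaving out MDA-MB-231 0 h replicate 1 gave 671 genes and leaving out MDA-MB-231 24 h replicate 1 gave 6. The 72 h count of 1, with 1385 at an unadjusted p under 0.05, became 751 without MDA-MB-231 0 h replicate 1 and 2 without either BT549 24 h array, and the STAT4 call ended without MDA-MB-231 0 h replicate 2 (adjusted p = 0.183) or either MDA-MB-231 72 h array (0.065 and 0.219). Median scaling ended it too, and over all alternatives its adjusted p ran from 0.0029 to 0.827.

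In MDA-MB-157 at 72 h, H3C8 and H3C4, which encode histone H3, both rose by 1.58 log2 (SE 0.29 and 0.27, limma adjusted p = 0.042 and 0.031), and near-identical copies leave open which H3 gene changed. RASGRP3, an exchange factor for Ras, rose by 1.36 (SE 0.20, adjusted p = 0.017). GCGR, the glucagon receptor gene, was detected on both arrays at 72 h and on neither at 0 h, and was at least 2.05-fold higher (adjusted p = 0.017), and TMPRSS3, a membrane serine protease, rose by 1.30 (adjusted p = 0.032), with its other probes at 0.03 to 0.91. BRD3OS fell by 1.09 (SE 0.20, adjusted p = 0.035), and H3C12, another histone H3 gene, was at least 1.56-fold lower (adjusted p = 0.031). Of the genes in mitosis, 32 of 32 G2/M members lay above 0 at 72 h with a median of 0.37 (camera adjusted p = 5.9e-11, and adjusted p = 0.80 with an estimated correlation), among them CENPF, a kinetochore protein, at 0.65. G1/S and DNA replication genes were at 0.37 at 24 h and 0.21 at 72 h (adjusted p = 1.5e-08 and 0.0026), and Fanconi anaemia and homologous recombination genes at 0.33 and 0.27 (adjusted p = 2.5e-04 and 0.012), with FANCI at 0.73 at 72 h. Both lists had adjusted p = 0.60 at 24 h and adjusted p = 0.80 at 72 h with an estimated correlation. Interferon-stimulated genes lay lower at 72 h, with 2 of 26 above 0 and a median of -0.49 (adjusted p = 6.9e-06, and adjusted p = 0.80 with an estimated correlation), and IFIT2 was at -1.22. At 24 h histone genes were at -0.41 (adjusted p = 5.2e-04) and metallothionein genes at 0.31 (adjusted p = 0.016). With an estimated correlation these 2 had adjusted p = 0.60 each. None of the directions in this line turned under median scaling. At 24 h limma called 0 genes, with 629 at an unadjusted p under 0.05 and no other tool run. At 72 h it called 12, 10 higher and 2 lower, with 1018 at an unadjusted p under 0.05. The count became 1 without MDA-MB-157 0 h replicate 1 or MDA-MB-157 72 h replicate 2, and no call was left without MDA-MB-157 0 h replicate 2 or with median scaling. Without background correction it was 19, and with array quality weights 67.

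In BT549, interferon-stimulated genes rose strongly at 72 h. OAS2, an antiviral oligoadenylate synthetase, rose by 3.35 log2 (SE 0.66, limma adjusted p = 0.016), with its other probes at 0.53 to 1.80, and MX1, an antiviral GTPase, by 3.33 (SE 0.65, adjusted p = 0.015). IFI44L rose by 3.08 (SE 0.47, adjusted p = 0.0032), IFIT3, which binds viral RNA complexes, by 2.71 (SE 0.32, adjusted p = 2.7e-04) and IFIT1 by 2.54 (SE 0.45, adjusted p = 0.011), while the other probes of IFI44L and IFIT1 read 0.83 and 0.45. All 26 measured interferon-stimulated genes lay above 0, with a median of 1.67, and 14 rose over all genes and 20 when adjusted over the list alone (camera adjusted p = 4.1e-33, and adjusted p = 0.067 with an estimated correlation). The largest falls were of other kinds. SOX11, a transcription factor of neural development, fell by 2.26 (SE 0.24, adjusted p = 1.4e-04), PCDHB2, a protocadherin, by 1.95 (SE 0.30, adjusted p = 0.0032), MEIOB, a meiotic single-strand DNA binding protein, by 1.75 (SE 0.29, adjusted p = 0.0047), KCNIP1, a potassium channel partner, by 1.68 (SE 0.29, adjusted p = 0.0083) and BEND6 by 1.78 (adjusted p = 0.013). The other probes of PCDHB2 and BEND6 read -0.67 and -0.40. G2/M and mitosis genes were lower, with 2 of 32 above 0, a median of -0.38 and ASPM, a spindle protein, fallen by 0.79 (adjusted p = 1.0e-07, and adjusted p = 0.52 with an estimated correlation). Metallothionein genes had a median of 0.91 with 8 of 8 above 0 and MT2A risen by 0.92 (adjusted p = 2.8e-06, and adjusted p = 0.11 with an estimated correlation).

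Smaller shifts in BT549 at 72 h covered 9 further lists. Medians above 0 were those of the anti-apoptotic (0.45, camera adjusted p = 0.017), histone (0.37, adjusted p = 0.016), lysosome and autophagy (0.27, adjusted p = 0.016), G1/S and DNA replication (0.23, adjusted p = 0.022), NF-kB and inflammatory cytokine (0.21, adjusted p = 0.025), p53 target (0.19, adjusted p = 0.025) and pro-apoptotic genes (0.16, adjusted p = 0.016), and those below 0 were of the cholesterol and lipid synthesis (-0.36, adjusted p = 0.0092) and NRF2 and glutathione genes (-0.26, adjusted p = 0.016). With an estimated correlation these lists had adjusted p = 0.11 to adjusted p = 0.64. CCL5, a chemokine of the NF-kB list, rose by 2.17, and H4C3 of the histone list fell by 1.57 against the direction of its list. Under median scaling the 7 medians above 0 turned below it, from -0.12 for histone genes to -0.48 for G1/S genes. With the authors' values the lysosome and G1/S medians also turned, to -0.12 and -0.13. Relative to all genes median scaling left the histone list at 0.34, the NF-kB list at 0.31, the pro-apoptotic list at 0.29, the p53 targets at 0.21, the anti-apoptotic list at 0.18, the lysosome list at 0.02 and the G1/S list at -0.01. At 24 h, LINGO2, a neuronal membrane protein, fell by 1.53 (SE 0.23, limma adjusted p = 0.034), and the sialyltransferase genes ST6GALNAC3 by 1.27 (other probe -0.51) and ST6GALNAC5 by at least 1.93-fold, as did LRMDA by at least 1.88-fold. G2/M and mitosis genes were already lower at -0.40, with 1 of 32 above 0 (camera adjusted p = 1.1e-13, and adjusted p = 0.54 with an estimated correlation). Histone (-0.26, adjusted p = 0.0070) and cholesterol and lipid synthesis genes (-0.24, adjusted p = 0.0070) were lower, and G1/S (0.23, adjusted p = 1.8e-05), Fanconi anaemia and homologous recombination (0.22, adjusted p = 0.0053), anti-apoptotic (0.25, adjusted p = 0.0070) and metallothionein genes (0.33, adjusted p = 0.027) higher, with adjusted p = 0.54 to adjusted p = 0.73 with an estimated correlation. The higher 4 turned to -0.21, -0.30, -0.27 and -0.16 under median scaling, and stood at 0.19, 0.10, 0.13 and 0.23 relative to all genes.

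At 72 h limma called 149 genes in BT549, 79 higher and 70 lower (53% higher), with 1849 at an unadjusted p under 0.05. The split was 5 higher and 39 lower (11.4%) with median scaling, and 42 and 305 (12.1%) with the authors' values. IFIT3, SOX11 and PCDHB2 stayed called without any 1 of the 24 arrays. Without BT549 0 h replicate 2 the count was 15, OAS2 was at 2.04 (adjusted p = 0.275, and 6.8e-04 to 0.388 over all alternatives) and MX1 at 2.02 (0.273, and 4.7e-04 to 0.391), and the interferon list mean was 1.13 (adjusted p = 0.12) in place of 1.71 (SE 0.34, adjusted p = 0.0044). Median scaling also ended the call of that mean (1.19, SE 0.42, adjusted p = 0.084), as its change was smaller and its error larger. The count was 67 without BT549 0 h replicate 1, 243 without BT549 72 h replicate 1 and 37 without BT549 72 h replicate 2. The last of these also ended the camera calls of 8 of the 12 lists, whereas the interferon, metallothionein and G2/M lists stayed called without any array. Without BT549 72 h replicate 2 the medians were 0.38 for metallothionein, 0.18 for histone, 0.15 for anti-apoptotic, 0.10 for NF-kB, -0.11 for NRF2 and -0.21 for cholesterol genes. Without BT549 72 h replicate 1 the NRF2 median was -0.42 and the lysosome median 0.11. Without BT549 0 h replicate 1 the G1/S median was 0.13, the NF-kB median 0.36 and the lysosome median 0.41, and without BT549 0 h replicate 2 the histone median was 0.19, the NF-kB median 0.02, the NRF2 median -0.41 and the lysosome median 0.01. With a replicate block within each line the 72 h count was 382 and the interferon list mean had adjusted p = 1.8e-04 (up to 0.12 over its alternatives), while ST6GALNAC3 at 24 h fell short (adjusted p = 0.072). The 24 h count of 4, with 820 at an unadjusted p under 0.05, became 1 without BT549 0 h replicate 2 or BT549 24 h replicate 2, and 2 without BT549 24 h replicate 1, either MDA-MB-157 24 h array or either HCC38 24 h array. No 24 h call was left without BT549 0 h replicate 1, either MDA-MB-157 0 h array, either MDA-MB-231 24 h array, either MDA-MB-231 72 h array or either HCC38 72 h array.

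In HCC38 at 72 h, RN7SK, the RNA that restrains the elongation factor P-TEFb, rose by 1.81 log2 (SE 0.29, limma adjusted p = 0.042), RNU1-3, a copy of the U1 spliceosomal RNA, by 2.82-fold (SE 0.27 log2, adjusted p = 0.044), the inflammatory cytokine gene TNF by 0.97 (SE 0.16, adjusted p = 0.044) and ZNF280A by 0.80 (adjusted p = 0.044). EDN2, an endothelin, fell by 1.82 (SE 0.31, adjusted p = 0.044), OPRK1, the kappa opioid receptor gene, by 1.33, DIO2, a thyroid hormone deiodinase, by 1.32 (SE 0.21, adjusted p = 0.042, other probe -0.75), ATG5, a core autophagy gene, by 1.17 and COX20, an assembly factor of cytochrome oxidase, by 1.04. Near-identical copies of RN7SK and RNU1-3 make their calls uncertain, as does the untested capture of small RNAs by the kits used. Histone genes lay lower at -0.61 with 0 of 15 above 0 and 6 fallen when adjusted over the list alone (camera adjusted p = 2.0e-05, and adjusted p = 0.48 with an estimated correlation), after -0.34 at 24 h. NF-kB and inflammatory cytokine genes were at 0.36 (adjusted p = 1.2e-04, and adjusted p = 0.48 with an estimated correlation). NRF2 and glutathione genes were at -0.35 (adjusted p = 0.0040, and adjusted p = 0.67 with an estimated correlation), with AKR1B10 at -1.87, and cholesterol and lipid synthesis genes at -0.33 (adjusted p = 0.0045, and adjusted p = 0.70 with an estimated correlation), with INSIG1 at -1.29. Ribosome biogenesis genes were at 0.31 with 17 of 17 above 0 (adjusted p = 1.2e-04), G2/M and mitosis genes at 0.26 (adjusted p = 8.4e-05), G1/S and DNA replication genes at 0.22 (adjusted p = 0.0048) and Fanconi anaemia and homologous recombination genes at 0.24 (adjusted p = 0.0040). With an estimated correlation these 4 had adjusted p = 0.48, adjusted p = 0.70, adjusted p = 0.74 and adjusted p = 0.67. The G2/M, G1/S and Fanconi medians turned to -0.05, -0.10 and -0.12 under median scaling, and stood at 0.17, 0.13 and 0.10 relative to all genes.

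At 24 h in HCC38 limma called 0 genes, with 655 at an unadjusted p under 0.05 and no other tool run, but 36 without HCC38 0 h replicate 1 and 1 without HCC38 24 h replicate 1. Lists above 0 then were G1/S and DNA replication (0.30, camera adjusted p = 2.5e-05), Fanconi anaemia and homologous recombination (0.18, 20 of 20 above 0, adjusted p = 3.9e-04), metallothionein (0.30, adjusted p = 0.0026) and ribosome biogenesis genes (0.20, adjusted p = 0.0048), and lists below 0 were histone (adjusted p = 0.0026), mesenchymal and extracellular matrix (-0.28, adjusted p = 0.0027), hypoxia and glycolysis (-0.19, adjusted p = 0.025) and cholesterol and lipid synthesis genes (-0.22, adjusted p = 0.044). With an estimated correlation these lists had adjusted p = 0.57 to adjusted p = 0.70. LOX, a collagen crosslinking enzyme, was at -1.03. The 4 medians above 0 turned to between -0.16 and -0.00 under median scaling, and to between 0.12 and 0.27 relative to all genes. At 72 h limma called 12 genes, 4 higher and 8 lower, with 1528 at an unadjusted p under 0.05. The count became 185 without HCC38 0 h replicate 1, and 6 without either MDA-MB-157 24 h array or either BT549 72 h array. It became 1 without HCC38 0 h replicate 2 or either BT549 0 h array, and no call was left without either HCC38 72 h array, either MDA-MB-157 0 h array, either MDA-MB-157 72 h array or either MDA-MB-231 72 h array. It was 67 without background correction and 3 with median scaling.

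Whether the lines differed in their change was tested directly. At 72 h limma's interaction test called 6 genes, with 1411 at an unadjusted p under 0.05, and in each the change in BT549 stood apart. IFIT3 was at 2.71 in BT549 against 0.91 in MDA-MB-231, -0.09 in HCC38 and -0.40 in MDA-MB-157 (SE 0.32 each, adjusted p = 0.017). USP18, a protease that removes ISG15, was at 2.01 in BT549 against 0.57, -0.13 and -0.73 (SE 0.26, adjusted p = 0.010), and XAF1, an interferon-induced pro-apoptotic gene, at 1.67 against -0.62, 0.34 and -0.30 (SE 0.24, adjusted p = 0.029). IL4I1, a secreted amino acid oxidase, was at 2.24 in BT549 (adjusted p = 0.010), PTCHD1 at 1.52 (adjusted p = 0.010) and SOX11 at -2.26 (adjusted p = 0.010), and in the other lines these 3 lay between -0.22 and 0.06. The interferon and G2/M list means did not pass the test of a difference between the lines (adjusted p = 0.067 each), and the G2/M mean was 0.52 in MDA-MB-231, 0.38 in MDA-MB-157, 0.25 in HCC38 and -0.39 in BT549. Without MDA-MB-231 0 h replicate 2 it was 0.17 in MDA-MB-231. At 24 h the interaction test called 0 genes, with 630 at an unadjusted p under 0.05, no other tool having been run. The 72 h interaction calls ended without BT549 0 h replicate 2 and did not hold as a set without BT549 72 h replicate 2. With median scaling the count at 72 h was 1. The count became 323 without MDA-MB-231 0 h replicate 1, 25 without BT549 0 h replicate 1, 31 without HCC38 0 h replicate 1 and 16 without either BT549 24 h array. At 24 h it became 79 without MDA-MB-231 0 h replicate 1, 3 without HCC38 0 h replicate 1 and 1 without MDA-MB-231 24 h replicate 1. Only RASGRP3 was called higher in more than 1 line at 72 h (1.36 in MDA-MB-157, 1.10 in BT549), and no gene was called in all 4. MDA-MB-231 had only 1 call at 72 h, so at most 1 gene could have been called in all 4. The small overlap does not show that the lines respond differently. Across genes, the 72 h changes of BT549 and HCC38 correlated at 0.33, those of HCC38 and MDA-MB-157 at 0.14, and the other pairs between -0.05 and 0.12. At 24 h BT549 and HCC38 correlated at 0.30, MDA-MB-231 and MDA-MB-157 at 0.24, and the other pairs between -0.04 and 0.09. These pairs share no arrays, and genes are not independent replicates. Under median scaling the median change of all genes at 24 h was -0.40 in BT549 and -0.28 in HCC38. It was 0.16 in MDA-MB-231 and 0.09 in MDA-MB-157, so the pairs that correlated most at 24 h also shifted the same way in brightness. At 72 h BT549 and HCC38 again shifted together (-0.47 and -0.22), while MDA-MB-157 shifted the other way (0.17). The part of brightness in these correlations was not tested.

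**Figure D3:**
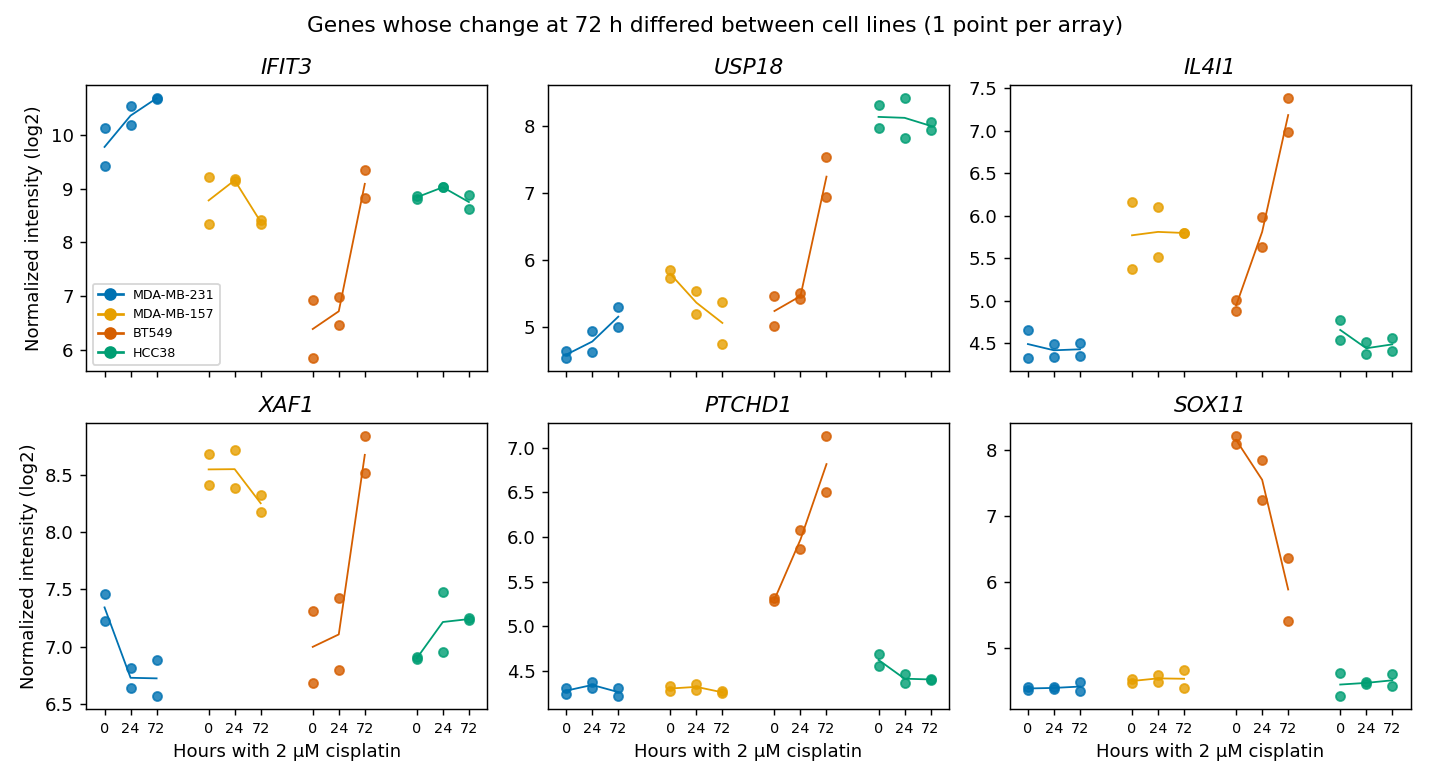
Log2 normalized intensity on each of the 24 arrays for the 6 genes whose change at 72 h differed between the lines, against hours of cisplatin; points are single arrays, colours are the cell lines and lines join the means of the 2 arrays per group. In BT549 IFIT3 rose by 2.71 and SOX11 fell by 2.26 at 72 h.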

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

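The changes of 6 genes at 72 h differed between the cell lines by limma's interaction test, which brought them here. The adjusted p was 0.0171 for IFIT3, 0.0104 for IL4I1, 0.0104 for PTCHD1, 0.0104 for SOX11, 0.0104 for USP18 and 0.0286 for XAF1, and BT549 stood apart in each. A further signal lay in probes without a gene name, which the comparisons do not use. Of 8649 such probes that passed the detection filter, limma called 2 in BT549 at 72 h and 0 in the average at 72 h, where 716 had an unadjusted p under 0.05.

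The interferon response of BT549 at 72 h was weighed against 3 technical causes, with all 3 tests set after the result was seen, since an earlier test of brightness ran on quantile-normalized values, which hold random lists near 0. If a single array had caused it, at least 1 of the 4 differences between a 72 h and a 0 h array would have been under 1 SE, and the lowest was 1.11 log2 (SE 0.34), on slide 2, against 2.32 on slide 1. If brightness or scaling had caused it, random lists of equal signal would have moved as far under median scaling, which keeps such a trend, and the highest median of 10000 such lists was -0.252 against 1.10, although the call of the list mean ended there, as the change shrank from 1.71 (SE 0.34) to 1.19 (SE 0.42, adjusted p = 0.084). If blood cells had been present, haematopoietic markers would have risen by more than 1, and their mean changed by 0.107 (SE 0.13). These values argue against each of the 3 as the whole cause, while a release of interferon after DNA damage and an infection of the culture were not told apart. The slide 1 pair held BT549 0 h replicate 2 and the slide 2 pair 0 h replicate 1, and these 2 arrays differed in interferon genes before the drug. Without 0 h replicate 2 the list median went from 1.67 to 1.30, OAS2 from 3.35 to 2.04 and MX1 from 3.33 to 2.02. The size of the rise thus depends on which 0 h array is the baseline.

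The distance between the 2 MDA-MB-231 arrays at 0 h was weighed after the replicates had been compared, with the tests of hybridisation and of the source of the higher genes set after their results could be seen and the other 2 set before. With a wrong time label, replicate 2 would lie as close to a 24 h or 72 h array as replicates do, and its lowest SD against the line's other 5 arrays was 0.493, above the highest replicate SD elsewhere, 0.448. With a weak hybridisation fewer probes would be detected, and the 19315 detected lay within the range of the other 5 arrays. RNA of another line would raise that line's markers, and compared with replicate 1 the 4 markers of BT549 had a median of 1.44, those of HCC38 1.40 and those of MDA-MB-157 -0.59. This prediction was thus met for BT549 and HCC38, so RNA of these lines remained possible, and neither stood out as the source. Of the 192 genes more than 2-fold above the other 5 arrays, 105 lay above all 18 arrays of BT549, HCC38 and MDA-MB-157. For those 105 this argues against RNA of these lines, in the states measured, as the source. For the rest of the 192 these lines were not excluded, and RNA from outside the series was not tested.

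Whether other assignments of the arrays within the lines would give as many calls was tested on 100 of 648 assignments, a test set before its result was known. At 24 h the real count was 2, the highest other was 11 and 9 of 100 were as large, so chance could not be excluded. At 72 h the real count was 179 and the highest other 84, and between 24 h and 72 h the real count was 22 and the highest other 3, with 1 of 100 as large in each, the real one itself.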

How the results depend on the processing

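Of the values of single genes under the alternatives, 3727 kept their side of the threshold, 899 fell short of it, 5 newly passed and 0 called genes turned, while genes not called were followed only by their side of the threshold. For gene lists the direction was camera's, relative to all other genes, and 1296 stayed, 147 fell short and 7 turned. The count of genes that differ between the lines at 0 h moved by less than 1.5 times throughout. All counts below are limma calls, and the cause of their moves was not tested. Counts without MDA-MB-231 0 h replicate 1 rest on replicate 2 alone as that line's 0 h baseline, and replicate 2 stood apart from the line's other arrays.

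Without background correction the counts were 0 at 24 h in BT549, 19 at 72 h in MDA-MB-157, 67 in HCC38, 352 for the average at 72 h, 46 for 72 h against 24 h and 12 for the difference between lines at 72 h. With normexp and an offset of 50 they were 0, 6, 27, 333, 41 and 11, and 4 for the average at 24 h. With median scaling they were 2 at 24 h in BT549, 0 in MDA-MB-231, 0 in MDA-MB-157, 44 in BT549 and 3 in HCC38 at 72 h, 0 for the average at 24 h, 0 at 72 h, 0 for 72 h against 24 h and 1 for the difference between lines. With the authors' values they were 0 at 24 h in BT549, 0 in MDA-MB-157 and 347 in BT549 at 72 h, 0, 51 and 1 for the averages (24 h, 72 h, 72 h against 24 h) and 2 for the difference between lines. The cause was not tested.

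With no detection filter (20046 genes) the counts were 2 at 24 h in MDA-MB-157, 0 at 72 h in MDA-MB-231 and 11 for 72 h against 24 h. With the stricter filter (10163 genes) they were 0 at 24 h in BT549, 1 in MDA-MB-157 and 0 in HCC38 at 72 h, 4 and 270 for the averages at 24 h and 72 h, and 2 for the difference between lines. With all probes they were 2 in MDA-MB-231 and 6 in HCC38 at 72 h, 14 for 72 h against 24 h and 11 for the difference between lines. The slide block gave 0 in HCC38 at 72 h, 4 for the average at 24 h and 14 for 72 h against 24 h. Array quality weights gave 2 at 24 h in BT549, 0 in MDA-MB-231 and 67 in MDA-MB-157 at 72 h, 1 for the average at 24 h and 11 for the difference between lines. These weights were the same for both arrays of a group, so this setting does not test for a single poor array.

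A replicate block shared by the lines moved the difference between lines at 72 h to 15. It gave 206 in BT549 at 72 h, 264 for the average at 72 h and 28 for 72 h against 24 h, and so moved these by less than 1.5 times. A replicate block within each line gave 5 in MDA-MB-231, 382 in BT549 and 115 in HCC38 at 72 h, 11, 504 and 55 for the averages and 65 for the difference between lines. Across genes, arrays with the same number deviated together in BT549, with correlations of 0.50, 0.42 and 0.38 between its times. In HCC38 these were 0.22, 0.17 and 0.07, and over the 12 pairs of times of the 4 lines they ran from -0.05 to 0.50 with 7 above 0.1. The labels do not say what a number stands for, so pairing is a hint from the data in BT549 and was not shown for the other lines.

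With fewer arrays the power falls, but how far this explains the counts was not tested. A line's own 6 arrays gave 0 calls for BT549 at 24 h and 0 for HCC38, BT549, MDA-MB-157 and MDA-MB-231 at 72 h. Line means as replicates gave 0, 45 and 1 for the averages, and slide 1 or slide 2 alone 0, 0 and 0. Leaving out MDA-MB-231 gave 0 at 24 h, 202 at 72 h and 25 for 72 h against 24 h, so fewer arrays did not lower every count. Leaving out MDA-MB-157 gave 0, 38 and 0, leaving out BT549 0, 1 and 4, and leaving out HCC38 0, 32 and 0. With 1 array left out, the lowest and highest counts at 24 h were 0 and 671 in MDA-MB-231, 0 and 0 in MDA-MB-157, 0 and 6 in BT549, 0 and 36 in HCC38, 0 and 130 for the average and 0 and 79 for the difference between lines. At 72 h they were 0 and 751, 0 and 16, 15 and 243, 0 and 185, 31 and 541, and 0 and 323 in the same order. They were 0 and 63 for 72 h against 24 h, and 9253 and 9979 at 0 h.

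By camera's direction the lists that turned were G1/S genes in BT549 at 72 h, at -0.48 with median scaling and -0.13 with the authors' values, lysosome genes there, at -0.44 and -0.12, and ATF4 genes in the average at 24 h, at 0.081 on slide 1 alone. Interferon-stimulated genes turned to -0.034 in the average at 72 h and -0.068 for 72 h against 24 h when BT549 was left out. With median scaling, under which the median of all genes moved to -0.47 in BT549 at 72 h, 5 further list medians there lay below 0 although camera's direction stayed. These were p53 target genes at -0.26, anti-apoptotic genes at -0.29, pro-apoptotic genes at -0.18, NF-kB genes at -0.16 and histone genes at -0.12, of which only the NF-kB list stayed called. The cause was not tested. Signal over background limits what could be called, since 38.7% to 46.4% of probes were detected per array.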

Other observations

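Further genes of BT549 at 72 h were picked after their values were seen, so they say nothing about a group. IFNB1, the interferon beta gene, was detected on both arrays at 72 h and on neither at 0 h, and was at least 2.07-fold higher (limma adjusted p = 0.017), and the RNA sensor genes RIGI and IFIH1, both in the interferon list, rose by 1.55 log2 (SE 0.24, adjusted p = 0.0032) and 1.92 (SE 0.36, adjusted p = 0.012). STING1 rose by 1.31 (SE 0.27, adjusted p = 0.022), the chemokine gene CCL5 by 2.17 (SE 0.46, adjusted p = 0.025) and HLA-B, which presents antigen, by 1.64 (SE 0.36, adjusted p = 0.029). CXCL10 (0.73) and CGAS (0.49), the enzyme that senses cytosolic DNA, did not pass. At 24 h IFIH1 was at -0.17 and RIGI at 0.30. Among the falls were CDKN1B, the cell cycle inhibitor p27, by 1.08 (SE 0.22, adjusted p = 0.023), and the histone chaperone gene ASF1A by 1.18 (SE 0.20, adjusted p = 0.0062). All 8 of these calls ended without BT549 0 h replicate 2, and also without BT549 72 h replicate 2. The highest adjusted p over the 24 arrays was 0.186 for IFNB1, 0.094 for RIGI, 0.206 for IFIH1, 0.326 for STING1, 0.351 for CCL5, 0.357 for HLA-B, 0.148 for CDKN1B and 0.110 for ASF1A, and with median scaling only ASF1A stayed called.

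Gene families were compared after their members had been noticed among the named genes. Of 15 tubulin genes, TUBB2B (0.75, limma adjusted p = 0.0080), TUBA4A (0.71, adjusted p = 0.048) and TUBB2A (0.65, adjusted p = 0.017) rose in the average at 72 h. The TUBB2B call stayed without any 1 array, while that of TUBA4A ended without any 1 of 18 arrays and that of TUBB2A without any 1 of 3. Over the family, 12 of 15 lay above 0 with a mean of 0.22 (SE 0.04) and a median of 0.07. Protocadherin genes had a mean of -0.17 (SE 0.06). Small nuclear and nucleolar RNAs had a mean of 0.01, with 2 of 196 risen, and of 421 zinc finger genes 3 fell without a shift of the family. Of 55 replication-dependent histone genes 3 rose from 24 h to 72 h, with a mean of 0.12 (SE 0.07) and a camera p of 0.247 with an estimated correlation, and their mean in the average at 72 h was -0.06 (SE 0.07).

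On MDA-MB-231 0 h replicate 2, 192 genes lay more than 2-fold above the line's other 5 arrays and 80 below them. TFF1 (3.51), GDF15 (3.09), TRIB3 (2.96), DDIT3 (2.86) and HSPA5 (2.77) were the highest, and TXNIP was at -3.60. The mean of the ATF4 list was 10.06 on it against 8.56 to 8.62 on the others.

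The idea that longer genes fell more at 72 h arose from the named genes, and the test of length was set after these values were seen, while those of brightness and signal level were set before. The median length was 39.5 kb for genes that fell, 16.6 kb for those that rose and 26.4 kb for all. Across 14793 genes, however, length and the average change correlated by rank at only -0.0471 (exact permutation p = 0.44), and at -0.0207 without MDA-MB-231 0 h replicate 2, so the test was not passed; what would count against it was narrowed after this value was known. The highest correlation in lines whose 72 h arrays were no dimmer than those at 0 h was 0.0386, which leaves brightness open. The median over 5 bins of signal level was -0.0442, which met the outcome set against signal level. As the correlation with length did not pass its own test, there was no shown pattern to explain, and no conclusion is drawn from these 2 values.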
